A study of Mus musculus with 6 samples.

How the data were processed

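Total RNA from the ear skin of 6 mice was measured on 6 one-colour arrays, 1 per mouse. Groups and replicate numbers come from the sample titles, with WT for the 3 mice labelled as NC16A sufficient (replicates 1, 2 and 3) and KO for the 3 labelled as NC16A deficient (replicates 1, 2 and 7). RNA was extracted with Qiagen RNeasy kits and measured with a Nanodrop, per the labels' protocols. How the RNA was labelled with Cy3 is not given in the sources used here. The design text states that the mice were matched for age and sex and names no litter or pairing.

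The deposited scanner files give, for each spot, the processed signal as an intensity, per the file headers. The headers record Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, array design 026655 and probe positions on mm9. In these values the software had subtracted background, corrected spatial trends within the array and replaced low values by surrogates, with no normalization between arrays, per the file headers. The deposited series matrix holds the same intensity values, equal to the processed signal for all 43340 features listed on each array. No spot was saturated. The slide of each array was read from the file headers. The median coefficient of variation of replicated spots lay between 2.32% and 4.64%.

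From each array's 43020 non-control spots, the 170 to 249 marked as outliers were left out, and the remaining spots of a probe were averaged (399 probes had 10 spots each). Of 39429 non-control probes, 40 had no usable spot and were left out. Values were log2 of the processed signal minus the array's 75th percentile. In intensity units this percentile was 5569 to 7056 on the WT arrays and 4068 to 4712 on the KO arrays. The 29601 probes well above background on at least 3 of the 6 arrays were kept, and each of 23675 genes was represented by its kept probe with the highest mean. Gene names came from a RefSeq gene table (GRCm38.p6, used for names only), which matched 26055 probes by accession, 3195 by symbol and 930 by synonym. Another 9249 probes kept the name in the scanner file.

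KO was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and no covariate. A gene passed at an adjusted p under 0.05. Residual degrees of freedom were 4 and prior degrees of freedom 2.64. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. The 30 lists, of 554 genes in all, were type 2 cytokines and their targets, itch mediators, neutrophil-attracting chemokines, the IL-1, IL-17 and IL-36 axis, interferon response, complement and MHC class II genes, markers of eosinophils, mast cells and basophils, neutrophils, monocytes and macrophages, dendritic and Langerhans cells, T cells, B and plasma cells, adipocytes, skeletal muscle, cartilage, endothelium, Schwann cells and nerve, and melanocytes, and genes of keratinocyte stress, the cornified envelope, basal keratinocytes, the cell cycle, hair follicle, sebaceous gland, dermal matrix, matrix proteases, immediate early and heat shock responses and red blood cells. Lists with under 5 measured genes were described and not tested, which left 29. A gene with no array well above background in 1 group is given as a bound, from the background level of that group's arrays, in the form "at least N-fold". Medians of the slide 1 comparison with such genes at their bound, from KO 1 alone, and the 2-fold counts with bounds were added after the data were seen.

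The rule for naming genes covered Col17a1 and Tslp always, with each array's values. It covered the 10 largest rises and the 10 largest falls in the fitted difference, among genes that passed and whose KO values lay wholly on 1 side of the WT values, without unnamed transcripts. In a list it covered up to 4 members with the smallest p that passed, or the 2 with the smallest p where fewer than 2 passed, and any member where 5 or fewer passed. The lists, this rule, the tests and the alternatives were fixed before the data were examined, except where stated.

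The alternatives were normexp background with an offset of 50, quantile normalization, the array median in place of the 75th percentile, and a 75th percentile over probes above background on all 6 arrays. They further covered no filter, a filter on all 6 arrays, the mean of a gene's probes, each probe tested alone, and the series matrix values. The fit was varied with replicate number as a block, slide as a fixed or a random block, an intensity trend, array weights, an adjusted p under 0.10, a 2-fold minimum, and each mouse left out in turn. Slide 1 alone, which is KO 1 against the 3 WT arrays, was added later. Steps ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

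The test was tried on simulated values for the same 23675 genes with 200 genes changed. It recovered 40% of genes changed 2-fold, 96% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold, of 50 each, with 10 false calls. A list raised in the simulation was called, and 0 of the other lists were. Simulated genes varied independently, whereas the estimated correlation within a real list reached 0.88 (muscle markers). The simulation therefore does not show how often the list test falsely calls lists of correlated genes.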

Results

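The series holds 6 one-colour expression arrays of total RNA from the ear skin of mice, 1 array per mouse. The 3 wild-type (WT) mice carried the NC16A segment of BP180 and the 3 knockout (KO) mice lacked it, per the labels. BP180 is collagen XVII, a transmembrane collagen of the hemidesmosome that anchors basal keratinocytes, and its gene is Col17a1. The labels number the WT mice 1, 2 and 3 and the KO mice 1, 2 and 7. Between 72.6% and 78.2% of the spots on each array were well above background. The median processed signal was 573, 445 and 482 in WT 1, 2 and 3, and 404, 383 and 368 in KO 1, 2 and 7. Each KO array was thus dimmer than each WT array before scaling. The arrays of the 3 WT mice and of KO 1 shared a slide (slide 1), and those of KO 2 and KO 7 were on another (slide 2). Differences are KO minus WT on the log2 scale with the standard error of the limma fit (SE), from 3 mice per group, unless stated otherwise. The comparison asks which transcripts differ in ear skin when the NC16A segment is missing, in a study whose title concerns skin inflammation.

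Col17a1 was read by 1 probe, and its signal did not differ between the groups. The probe (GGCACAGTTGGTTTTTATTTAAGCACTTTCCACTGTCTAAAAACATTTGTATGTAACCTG) lies on chromosome 19 from 47720894 to 47720953 of mm9, on the minus strand. Its log2 signal relative to the array's 75th percentile was 4.42 ± 0.045 (SD, n = 3) in WT and 4.30 ± 0.19 (SD, n = 3) in KO. The arrays of WT 1, 2 and 3 gave 4.41, 4.39 and 4.47, and those of KO 1, 2 and 7 gave 4.48, 4.31 and 4.10. The difference of -0.13 ± 0.14 had a 95% confidence interval from -0.46 to 0.21 (adjusted p = 0.58), and within slide 1 it was 0.05. The extent of the deleted segment is not given in the sources used here, so whether this probe lies inside it is unknown and its signal checks no label. Tslp, which encodes an epithelial cytokine of type 2 and itch responses, was read by a probe on chromosome 18 from 32978885 to 32978944 of mm9 (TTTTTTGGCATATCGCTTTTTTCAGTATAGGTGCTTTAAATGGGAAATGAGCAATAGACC). Its difference was -0.17 ± 0.24 (adjusted p = 0.66), and within slide 1 it was -0.46. Its log2 signal was -2.65, -3.23 and -3.07 in WT 1, 2 and 3, and -3.44, -3.29 and -2.73 in KO 1, 2 and 7. Both Xist probes were well above background on all 6 arrays. The probes of Ddx3y, Eif2s3y and Kdm5d were not well above background on any array, and 1 of 2 Uty probes was so on 1 array, KO 2. No other Y-linked genes were examined, and the design text states that age and sex were matched.

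Hair follicle and shaft genes, keratinocyte stress genes and neutrophil genes were prominent among those higher in KO. Of 23675 genes tested, 468 rose and 92 fell at an adjusted p under 0.05, and 419 of the former and 63 of the latter differed by at least 2-fold, or 416 and 54 with genes at background set to their bound. The genes named next were taken by the fitted difference, and where a gene was at background in 1 group its rank is not established. The largest fitted rise was in Uox, which encodes urate oxidase (6.23 ± 0.56, 74.9-fold, adjusted p = 0.0045), and the other of its 2 probes gave 4.85. The Uox signal was -7.81, -7.54 and -5.65 in WT 1, 2 and 3. In WT 1 and WT 2 the lowest signal well above background was -8.32 and -7.62, so the size of this rise is uncertain. Rises were also seen in the hair keratin-associated protein genes Krtap4-6 (at least 23.5-fold), Krtap22-2 (5.12 ± 0.64) and Krtap4-9 (5.09 ± 0.54), and in Krt26, a keratin gene of the inner root sheath (5.32 ± 0.67; well above background on 2 of 3 WT arrays). Sprr2k (at least 8.21-fold) and Sprr2b (at least 12.5-fold), which encode cornified envelope proteins, were not well above background on any WT array. Cstdc4 (4.92 ± 0.87), of the cystatin family of protease inhibitors, Ankk1 (4.89 ± 0.26) and the follicle gene Tchhl1 (4.85 ± 0.41) rose as well. Among genes well above background in both groups, the largest falls were in Cyp2g1, a cytochrome P450 gene (-3.41 ± 0.35), Serpinb6e (-3.30 ± 0.29) and the G protein subunit gene Gng13 (-3.16 ± 0.33). Mymx, which encodes a myoblast fusion protein (-2.89 ± 0.23), and the hepcidin gene Hamp2 (-2.66 ± 0.26) fell too. The antimicrobial peptide gene Leap2 (at least 5.73-fold lower, adjusted p = 0.0019), Pmp2 (at least 2.40-fold), Fthl17d (at least 1.95-fold), S100g (at least 1.45-fold) and Klhl14 (at least 2.25-fold) were not well above background on any KO array.

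All 560 genes that passed had KO values wholly on 1 side of the WT values. Of all genes, 35.4% had, against 10% by chance. At an unadjusted p under 0.05 there were 6301 genes. With slide as a block, which sets KO 1 against the WT arrays, 158 genes were higher and 10 lower, of which 143 and 7 were among the calls above. Within slide 1 the difference was 6.16 for Uox, 4.47 for Ankk1, 4.97 for Tchhl1, -3.53 for Cyp2g1 and -3.31 for Gng13. With the block Ankk1 and Tchhl1 passed, and Uox (adjusted p = 0.064), Cyp2g1 (adjusted p = 0.077) and Gng13 (adjusted p = 0.084) did not. Without WT 1 there were 301 genes higher and 54 lower, without WT 2 183 and 19, and without WT 3 217 and 19. Without KO 1 there were 717 and 254, without KO 2 219 and 23, and without KO 7 417 and 53. Without KO 1, all WT arrays were on slide 1 and all KO arrays on slide 2, so that fit cannot tell slide from group. Of the 45 genes that passed and that the naming rule covers, 24 passed in each of these 6 fits, and 16 passed and 29 did not with slide as a block. Among the 20 above, those that did not were Krt26 (without WT 2 or KO 2), Krtap22-2 (without WT 3 or KO 2), Sprr2k (without any WT mouse or KO 7), Sprr2b (without WT 1, WT 2 or KO 2), Cstdc4 (without any WT mouse or KO 2), Pmp2 (all but without WT 1) and Klhl14 (without WT 2, WT 3, KO 2 or KO 7), with highest adjusted p of 0.058, 0.063, 0.12, 0.074, 0.15, 0.098 and 0.086.

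**Figure D1:**
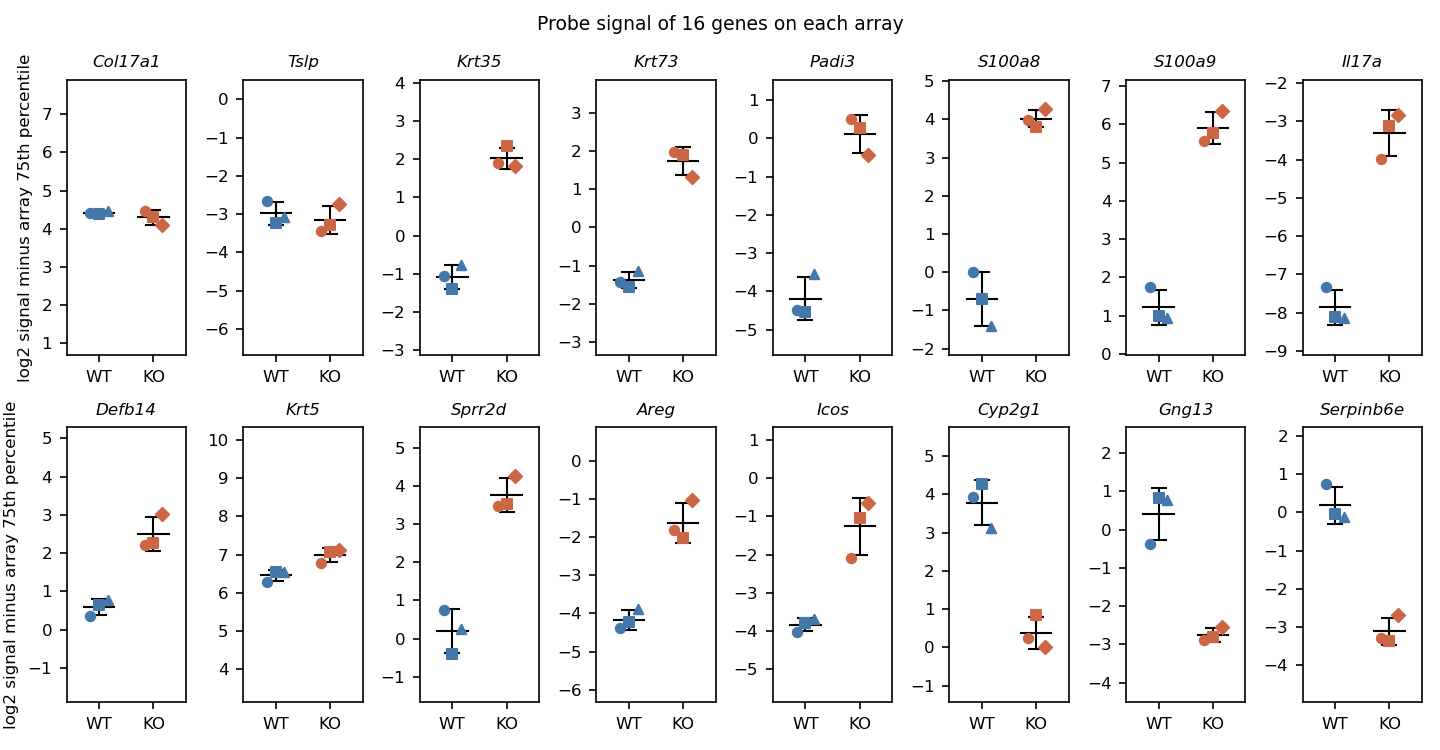
Log2 probe signal minus the array's 75th percentile for 16 genes, with 1 point per mouse (blue WT, red KO; the shape gives the replicate number) and the group mean ± SD (n = 3). Col17a1 and Tslp overlap between the groups, whereas the 3 KO values of S100a8, S100a9, Krt35, Krt73, Padi3 and Il17a lie above all 3 WT values and those of Cyp2g1, Gng13 and Serpinb6e below.

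Hair follicle and hair shaft genes formed the list with the most members that passed, all of them higher in KO. Of 27 measured genes, 22 rose, 0 fell and 5 did not pass, and 23 rose when adjusted over the list alone. The inner root sheath and hair shaft keratin genes Krt82 (3.21 ± 0.20), Krt35 (3.099 ± 0.22) and Krt73 (3.11 ± 0.22) each had an adjusted p of 0.0019. Padi3, whose enzyme citrullinates proteins of the inner root sheath, rose by 4.31 ± 0.35 (adjusted p = 0.0032). The Krt35 signal was -1.07 ± 0.31 (SD, n = 3) in WT and 2.03 ± 0.27 (SD, n = 3) in KO. The 5 that did not pass were Krt72, Krt81, Krt85, Msx2 and Foxn1, and they were chosen after their values were seen. The median of the list was 3.57, or 3.56 with genes at background set to their bound (camera adjusted p = 1.1e-18; adjusted p = 0.54 with an estimated correlation). The median within slide 1 was 4.16, or 4.06 with bounds (adjusted p = 1.1e-33 with slide as a block), with 3.09 for Krt82, 2.98 for Krt35, 3.35 for Krt73 and 4.70 for Padi3, which all passed with the block.

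Keratinocyte stress and hyperproliferation genes were higher in KO. Of 32 measured genes, 9 rose, 0 fell and 23 did not pass. When adjusted over the list alone, 27 rose and 1 fell. The cornified envelope gene Sprr2d rose by 3.55 ± 0.35 (adjusted p = 0.0057), the gap junction gene Gjb2 by 2.12 ± 0.23 (adjusted p = 0.0080) and the growth factor gene Areg by 2.55 ± 0.28 (adjusted p = 0.0088). Sprr2b rose at least 12.5-fold (adjusted p = 0.017), though it did not pass without WT 1, WT 2 or KO 2 (highest adjusted p = 0.074). The median was 2.23, and 30 of 32 members were higher in KO (camera adjusted p = 3.6e-11; adjusted p = 0.54 with an estimated correlation). On slide 1 alone the stress genes had a median of 2.28 (adjusted p = 3.0e-16 with slide as a block), with 3.28 for Sprr2d, 2.19 for Gjb2 and 2.36 for Areg. None of these genes passed with the block (adjusted p = 0.085, 0.098 and 0.13), nor did Sprr2b (adjusted p = 0.22).

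Neutrophil markers were higher in KO, led by the genes of calprotectin, an antimicrobial protein pair that stressed keratinocytes also make. S100a9 rose by 4.69 ± 0.30 (adjusted p = 0.0019) and S100a8 by 4.72 ± 0.35 (adjusted p = 0.0023). Stfa1, which encodes a stefin, rose by 3.43 ± 0.28 (adjusted p = 0.0031), and the iron-binding lipocalin gene Lcn2 by 2.72 ± 0.34 (adjusted p = 0.014). Lcn2 did not pass without WT 2 or without KO 2 (highest adjusted p = 0.072). Of 18 measured markers, 8 rose, 0 fell and 10 did not pass, and 13 rose when adjusted over the list alone. The median was 1.99 (camera adjusted p = 9.4e-08; adjusted p = 0.55 with an estimated correlation). The mean of the list relative to the WT mean was 2.92 in KO 7, 1.89 in KO 1 and 1.95 in KO 2, and without KO 7 the difference was 1.92 (adjusted p = 7.0e-08). For KO 1 against the WT arrays of its slide the median was 1.82 (adjusted p = 3.0e-08 with slide as a block), with 4.36 for S100a9, 4.69 for S100a8, 2.92 for Stfa1 and 2.32 for Lcn2, of which only Lcn2 did not pass with the block (adjusted p = 0.19).

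The chemokines and growth factors that draw neutrophils had a median of 3.59, or 3.02 with genes at background set to their bound. The mean of the list relative to the WT mean, genes at background included, was 5.09 in KO 7 against 2.38 in KO 1 and 2.44 in KO 2, and without KO 7 the difference of means was 2.41 (adjusted p = 5.2e-07). Csf3, the gene of granulocyte colony-stimulating factor, rose at least 3.95-fold (adjusted p = 0.040) and was not well above background on any WT array. It did not pass without WT 1, WT 2, WT 3 or KO 1 (highest adjusted p = 0.15). Cxcl1 differed by 2.72 ± 0.52 and did not pass (adjusted p = 0.053). Of 8 measured genes, 1 rose, 0 fell and 7 did not pass, all 8 were higher in KO, and 7 rose when adjusted over the list alone (camera adjusted p = 2.4e-04; adjusted p = 0.68 with an estimated correlation). Within slide 1 the median was 2.28, or 2.06 with bounds (adjusted p = 0.0015 with slide as a block), with 2.04 for Cxcl1, and Csf3 did not pass with the block (adjusted p = 0.42).

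Genes of the IL-1, IL-17 and IL-36 axis were higher in KO. Il17a, the T cell cytokine that acts on keratinocytes, rose by 4.55 ± 0.36 (adjusted p = 0.0027). Its signal was -7.86 ± 0.46 (SD, n = 3) in WT, where 1 of 3 arrays was well above background, and -3.31 ± 0.60 (SD, n = 3) in KO. The epithelial defensin genes Defb14 (1.91 ± 0.25, adjusted p = 0.016) and Defb3 (4.51 ± 0.61, adjusted p = 0.019) and the cytokine gene Il20 (1.69 ± 0.26, adjusted p = 0.029) rose as well. Defb14 did not pass without any of the 3 WT mice, Defb3 without WT 2 or WT 3, and Il20 without any WT mouse or KO 2, with highest adjusted p of 0.075, 0.086 and 0.12. Of 20 measured genes, 6 rose, 0 fell and 14 did not pass, and 11 rose when adjusted over the list alone. In the mean, 14 of the 20 were higher in KO and 6 were lower. The median was 1.51 (camera adjusted p = 6.6e-04; adjusted p = 0.54 with an estimated correlation). The axis had a median of 0.80 within slide 1 (adjusted p = 1.0e-05 with slide as a block), with 3.88 for Il17a, 1.62 for Defb14, 4.90 for Defb3 and 1.20 for Il20. Il17a passed with the block (adjusted p = 0.023), and Defb14, Defb3 and Il20 did not (adjusted p = 0.21, 0.15 and 0.25).

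T cell markers were higher by less, with a median of 0.48. The costimulatory receptor gene Icos rose by 2.58 ± 0.36 (adjusted p = 0.021), and its other probe gave 2.33. Cd6 rose by 2.31 ± 0.34 (adjusted p = 0.026), but its other probe gave -0.04. Ctla4, the gene of an inhibitory receptor, rose at least 2.64-fold (adjusted p = 0.034). Icos and Cd6 did not pass without any WT mouse or KO 2, and Ctla4 without WT 2, WT 3, KO 2 or KO 7, with highest adjusted p of 0.087, 0.11 and 0.13. Of 20 measured markers, 3 rose, 0 fell and 17 did not pass, 7 rose when adjusted over the list alone, and 18 were higher in KO (camera adjusted p = 6.5e-04; adjusted p = 0.75 with an estimated correlation). T cell markers had a median of 0.30 within slide 1 (adjusted p = 0.035 with slide as a block), with 1.75 for Icos and 1.67 for Cd6. With the block Icos, Cd6 and Ctla4 did not pass (adjusted p = 0.062, 0.23 and 0.37).

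Matrix proteases and their inhibitors had a median of 0.47. The collagenase gene Mmp13 rose by 1.82 ± 0.26 (adjusted p = 0.022) but did not pass without WT 1, WT 3 or KO 7 (highest adjusted p = 0.084). The aggrecanase gene Adamts4 differed by 1.89 ± 0.36 and did not pass (adjusted p = 0.052). Of 15 measured genes, 1 rose, 0 fell and 14 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.80 with an estimated correlation). The list did not pass without WT 2 (adjusted p = 0.058), without WT 3 (adjusted p = 0.11) or without KO 7 (adjusted p = 0.12). Within slide 1 its median was 0.21 (adjusted p = 0.063 with slide as a block), with 2.08 for Mmp13, which did not pass with the block (adjusted p = 0.12), and 1.36 for Adamts4.

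Adipocyte, skeletal muscle and cartilage markers were lower in KO as lists, while no member passed alone. All 15 adipocyte markers were lower in KO, with a median of -0.86 (camera adjusted p = 8.8e-05; adjusted p = 0.76 with an estimated correlation). Adiponectin, from Adipoq, differed by -1.31 ± 0.38 (adjusted p = 0.11) and leptin, from Lep, by -1.50 ± 0.44 (adjusted p = 0.11). Of 21 muscle markers 18 were lower, with a median of -0.54 (camera adjusted p = 0.0030; adjusted p = 0.98 with an estimated correlation). The myosin gene Myh1 differed by -0.54 ± 0.16 (adjusted p = 0.11) and the myoglobin gene Mb by -0.65 ± 0.21 (adjusted p = 0.13). Without WT 2 the muscle list had an adjusted p of 0.089, and without KO 7 of 0.12, and over the fits without 1 mouse its mean ranged from -0.82 to -0.17, against -0.52 with all mice. Of 17 measured cartilage markers 11 were lower and 4 fell when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0066; adjusted p = 0.54 with an estimated correlation). The cartilage matrix gene Comp differed by -0.62 ± 0.14 (adjusted p = 0.069) and Col9a1 by -1.12 ± 0.26 (adjusted p = 0.075), although the other Col9a1 probe gave 0.03. Within slide 1 the medians were -0.37 for adipocyte, -0.13 for muscle and -0.18 for cartilage markers, with adjusted p of 0.061, 0.55 and 0.063 with slide as a block. Fat, muscle and cartilage are layers of the ear, and the mean of the muscle list was -0.61 in WT 1 and -0.09 in KO 1 relative to the WT mean.

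**Figure D2:**
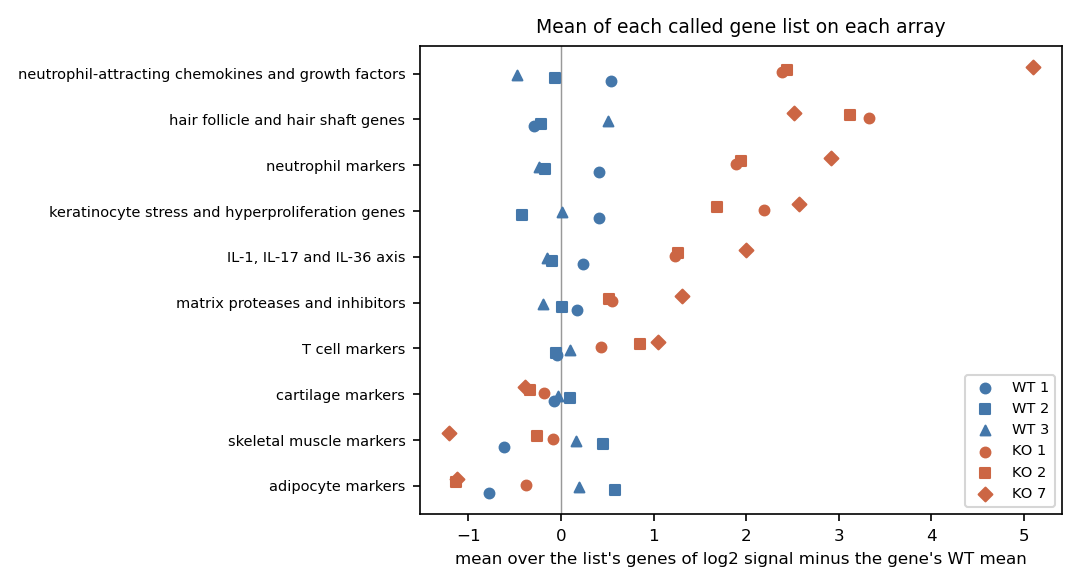
Mean over each list's measured genes of the log2 signal minus the gene's WT mean, with 1 point per mouse, for the 10 lists that passed. The KO arrays lie above all WT arrays in the 7 lists higher in KO, KO 1 included, and WT 1 lies below KO 1 in the adipocyte and muscle lists.

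Type 2 cytokines and their targets did not pass as a list. The median of the 24 measured genes was 0.24 (camera adjusted p = 0.86), and within slide 1 it was -0.18. Areg, also a keratinocyte stress gene, was the only member that rose, by 2.55 ± 0.28 (not past the threshold with slide as a block), and 0 fell over all genes tested, while 1 rose and 1 fell when adjusted over the list alone. The eosinophil chemokine gene Ccl11 differed by -1.31 ± 0.26 and did not pass (adjusted p = 0.056). The itch mediators had a median of 0.20 over 13 genes (camera adjusted p = 0.86), and the differences of their genes with the smallest p were 1.25 ± 0.37 for Artn (adjusted p = 0.11) and -0.59 ± 0.20 for F2rl1 (adjusted p = 0.14). The 8 eosinophil markers had a median of -0.15 (camera adjusted p = 0.86), with 0.68 ± 0.20 for Ear6 (adjusted p = 0.11) and -0.70 ± 0.28 for Siglecf (adjusted p = 0.18). The 14 mast cell and basophil markers had a median of 0.68 (camera adjusted p = 0.28), with 1.23 ± 0.34 for the IgE receptor gene Fcer1a (adjusted p = 0.10) and 1.95 ± 0.56 for Tph1 (adjusted p = 0.11). Without KO 1, where slide and group coincide, the mast cell list passed (camera adjusted p = 0.022), and within slide 1 its median was -0.01.

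Markers of other leukocytes and of interferon and complement did not pass as lists by camera, and no member of these lists passed over all genes tested. The 18 monocyte and macrophage markers had a median of 0.03 and a mean of -0.01, which differ in sign, with camera on the lower side (adjusted p = 0.73), with -1.05 ± 0.29 for Cd68 (adjusted p = 0.10) and -0.69 ± 0.21 for Fcgr3 (adjusted p = 0.12). The 12 dendritic and Langerhans cell markers had a median of 0.35 (camera adjusted p = 0.71), with 1.03 ± 0.30 for the migration receptor gene Ccr7 (adjusted p = 0.11) and 0.75 ± 0.25 for Fscn1 (adjusted p = 0.14). The 11 genes of MHC class II presentation had a median of 0.14. Camera, which compares a list's test statistics with those of all other genes, put this list on the lower side (adjusted p = 0.96). H2-Aa differed by -0.92 ± 0.20 (adjusted p = 0.067) and H2-Eb2 by 0.75 ± 0.19 (adjusted p = 0.088). When adjusted over the list alone, 1 member rose and 2 fell. The 11 B and plasma cell markers had a median of 0.68 (camera adjusted p = 0.37), with 2.25 ± 0.52 for Blk (adjusted p = 0.075; well above background on 2 of 3 WT arrays) and -0.47 ± 0.13 for Pou2af1 (adjusted p = 0.099). By fry the list passed (adjusted p = 0.023), and 5 members rose and 1 fell when adjusted over the list alone. Blk passed with slide as a block, with 3.47 within slide 1 (adjusted p = 0.023). The 25 interferon response genes had a median of 0.05 (camera adjusted p = 0.95), with 1.11 ± 0.22 for Cxcl10 (adjusted p = 0.056) and -0.72 ± 0.16 for Irf7 (adjusted p = 0.067), while 3 rose and 2 fell when adjusted over the list alone. The 14 complement genes had a median of 0.06, also on the lower side by camera (adjusted p = 0.86), with 0.53 ± 0.20 for C4b (adjusted p = 0.16). The complement list passed on the lower side without KO 7 (mean -0.22, adjusted p = 0.042).

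The epidermal and dermal lists other than stress genes did not pass. The 39 cornified envelope and barrier lipid genes had a median of 0.20 (camera adjusted p = 0.33), with -0.78 ± 0.19 for the filaggrin family gene Flg2 (adjusted p = 0.086) and 1.16 ± 0.29 for Krt1 (adjusted p = 0.087). The 16 basal keratinocyte and hemidesmosome genes had a median of 0.05 (camera adjusted p = 0.95), with 0.54 ± 0.15 for Krt5 (adjusted p = 0.10; the other probe gave -0.84) and 0.50 ± 0.15 for Krt14 (adjusted p = 0.11). The 31 cell cycle genes had a median of 0.03, on the lower side by camera (adjusted p = 0.95), with 0.43 ± 0.16 for Tyms (adjusted p = 0.15) and 0.32 ± 0.15 for Rrm2 (adjusted p = 0.22). Among 14 sebaceous gland genes (median 0.02, camera adjusted p = 0.96) the fatty acid elongase gene Elovl3 rose by 1.56 ± 0.17 (adjusted p = 0.0085), but not without WT 2 (adjusted p = 0.053) or with slide as a block (adjusted p = 0.099), and the wax synthase gene Awat2 differed by -1.49 ± 0.32 (adjusted p = 0.066). Among 20 fibroblast and dermal matrix genes (median 0.30, camera adjusted p = 0.86) the dermatopontin gene Dpt fell by 1.18 ± 0.20 (adjusted p = 0.038), and the fibrillin gene Fbn1 differed by -0.96 ± 0.19 (adjusted p = 0.056). Dpt did not pass in any of the fits without 1 mouse except without KO 1, where slide and group coincide. Its highest adjusted p in these limma fits was 0.16, and it did not pass with slide as a block. The 11 Schwann cell and nerve markers had a median of -0.11 (camera adjusted p = 0.093), with -0.70 ± 0.24 for Cdh19 (adjusted p = 0.14). The 17 endothelial markers had a median of 0.27 (camera adjusted p = 0.80), with 0.67 ± 0.17 for Vcam1 (adjusted p = 0.086) and 0.74 ± 0.20 for Selp (adjusted p = 0.099). The 8 melanocyte markers had a median of 0.76 (camera adjusted p = 0.58), with 0.82 ± 0.24 for Oca2 (adjusted p = 0.11) and -0.37 ± 0.14 for Tyr (adjusted p = 0.17). The 17 immediate early and heat shock genes had a median of -0.04 and a mean of 0.05, which differ in sign, with camera on the lower side (adjusted p = 0.95), with 0.59 ± 0.19 for Gadd45b (adjusted p = 0.13) and -0.70 ± 0.28 for Hspa1a (adjusted p = 0.18).

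**Figure D3:**
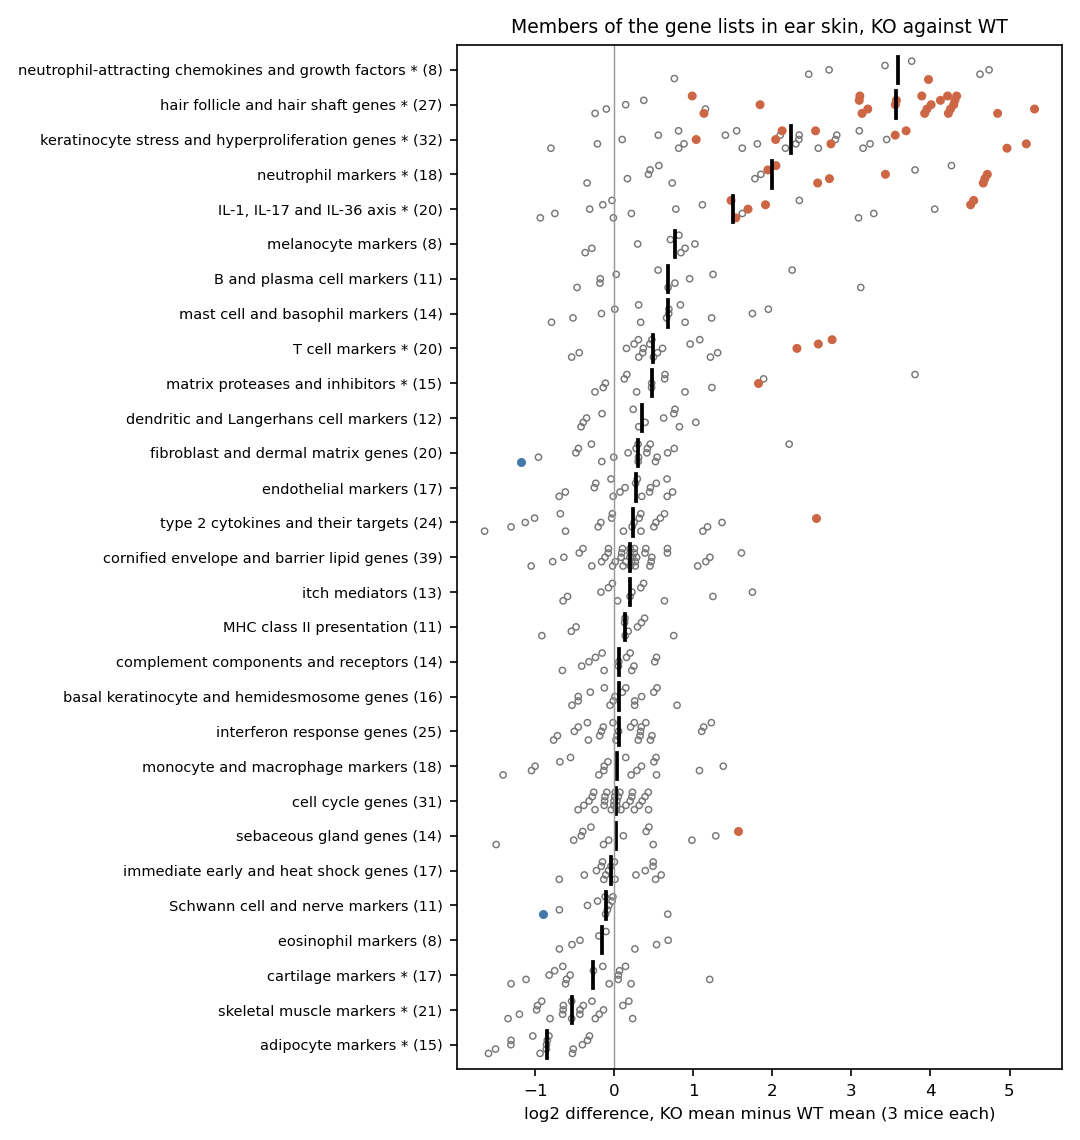
Log2 difference, KO mean minus WT mean (3 mice each), of each measured member of the 29 tested lists; filled points passed an adjusted p under 0.05 over all genes, the bar is the list median, and a star marks a camera adjusted p under 0.05. Hair follicle genes, with a median of 3.57 and 22 filled points, and adipocyte markers, with a median of -0.86 and 0 filled points, lie near the ends.

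Of the 29 lists tested with camera at a preset correlation, 7 were higher and 3 lower in KO. None passed by camera with an estimated correlation, under which the smallest adjusted p was 0.54. By fry, which asks whether a list's own genes move 1 way, 5 lists passed, namely hair follicle, keratinocyte stress, neutrophil, IL-1, IL-17 and IL-36 and B and plasma cell genes. With slide as a block 6 of the 7 higher lists passed and 0 of the 3 lower ones. Across all genes, correlations lay between 0.989 and 0.993 within WT, between 0.984 and 0.992 within KO and between 0.962 and 0.984 between the groups. The first principal component, with 61.4% of the variance, put all WT arrays on 1 side and all KO arrays on the other, with KO 1 nearest to WT and KO 7 farthest. Within KO, only KO 1 was on slide 1. A limma fit for slide within KO cannot tell slide from mouse, so it neither shows nor excludes a slide effect. The number of arrays limits the precision of all values above.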

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

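Each alternative changed 1 choice. The slide 1 comparison was chosen after seeing the data, and the others before. The cause of the changes given here was not tested, except where the alternative's own construction (fewer mice, a looser threshold, more genes tested) shows it. No gene that passed changed sign in any alternative that tested it. The 45 genes of the naming rule that passed kept their direction and their side of the threshold in 819 of 1022 comparisons and were no longer past it in 203. The 44 that did not pass stayed so in 915 of 1011, passed in 93 and changed sign in 3. The 10 lists that passed did so in 196 of 229 comparisons and never changed sign. The 19 others stayed so in 378 of 437, passed in 8 and had a mean of the other sign in 51. The series matrix values moved nothing, since they are the same values, and are no test of stability.

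Against 468 genes higher and 92 lower, normexp background gave 860 higher and 135 lower, the array median 149 lower beside 389 higher, no filter 269 and 27 (31682 genes tested), array weights 4545 and 3076, and an adjusted p under 0.10 1569 and 471. Leaving out 1 mouse gave 183 to 717 higher and 19 to 254 lower. The highest counts came without KO 1, where slide and group coincide. The higher share of the calls was 83.6%, and 72.3% with the array median and 59.6% with array weights. The median of all genes was 0.054, and ranged from -0.083 with the array median and -0.041 with quantile normalization to 0.11 with normexp and 0.12 without a filter, so small list shifts are relative to it.

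With slide as a fixed block there were 158 genes higher and 10 lower, with 1893 at an unadjusted p under 0.05 in limma, and 0 lists lower. This fit rests on KO 1 alone against 3 WT arrays. Slide 1 alone gave 157 and 8, and 1 list lower, cell cycle genes, which was not among the 3. The higher share was 94.1% with the block and 95.2% on slide 1. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 were lower.

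The replicate number as a block gave 0 genes higher and 0 lower in limma, with 4516 at an unadjusted p under 0.05, since only numbers 1 and 2 occur in both groups and the block leaves few arrays to compare. Deviations from the group mean correlated at 0.083 and 0.054 between mice of the same number and at 0.079 and 0.038 between mice of different numbers. These values show no sign of pairing by number, but 2 shared numbers are too few to exclude it.

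Adjusted p over the alternatives to the fit ranged from 1.1e-33 to 7.9e-13 for hair follicle genes, 7.8e-18 to 5.7e-07 for keratinocyte stress genes, 8.3e-10 to 5.1e-06 for neutrophil markers, 2.4e-07 to 0.0015 for neutrophil chemokines, 7.4e-07 to 0.019 for the IL-1, IL-17 and IL-36 axis and 4.0e-05 to 0.042 for T cell markers. It reached 0.34 for matrix proteases, 0.083 for adipocyte, 0.072 for cartilage and 0.55 for muscle markers.

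List means of the other sign came from lists that had not passed. They were 0.073 for eosinophil and 0.018 for monocyte markers with normexp; -0.11 for MHC class II, -0.061 for complement, -0.082 for basal keratinocyte and -0.017 for cell cycle genes with quantile normalization. With the array median they were -0.0032 for type 2, -0.10 for MHC class II, -0.015 for interferon, -0.13 for complement, -0.074 for basal keratinocyte, -0.11 for cell cycle and -0.090 for immediate early genes. With the mean of a gene's probes Krt5 was -0.15, as its probes disagree, and complement -0.0095. The replicate block gave -0.016 for interferon, -0.16 for complement and -0.11 for immediate early genes. The fixed slide block and slide 1 alone, which give the same estimates, gave 0.055 for Col17a1, -0.11 for type 2, -0.16 for MHC class II, -0.13 for complement, -0.0012 for itch, -0.17 for cell cycle, -0.025 for melanocyte and -0.031 for immediate early genes. The random slide block gave -0.0015 for complement. Array weights gave 0.083 for eosinophil markers, -0.12 for interferon, -0.30 for complement, -0.086 for endothelial and -0.18 for immediate early genes.

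Without 1 mouse the means ranged from -0.24 to 0.13 for monocyte, -0.13 to 0.070 for eosinophil, -0.22 to 0.16 for complement, -0.065 to 0.16 for immediate early, -0.029 to 0.14 for MHC class II and -0.14 to 0.16 for cell cycle genes. Complement passed on the lower side without KO 7 (camera adjusted p = 0.042). Mast cell markers passed on the higher side without KO 1 (camera adjusted p = 0.022), where slide and group coincide. Signal over background limits 47 genes at background in WT and 108 in KO, for which only a bound on the fold can be given.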

Other observations

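The family counts, both tests against a slide effect, the dilution tests and the splits of the arrays were chosen after the result was seen, and the other tests before.

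Gene families named by a shared stem were compared with all named genes tested, without transcripts that have only clone or accession names. Of 231 families, 3 held more genes higher in KO than their share by a one-sided Fisher's exact test. The hair keratin-associated protein family Krtap had 46 of 50 genes higher, with a median of 3.79 (Fisher's exact test, adjusted p = 1.9e-76). The only one of its members below WT in the mean was Krtap3-2 (-0.36), named after its value was seen. The keratin family Krt had 21 of 50 genes higher, with a median of 1.11 (Fisher's exact test, adjusted p = 1.7e-22). The small proline-rich family Sprr had 5 of 13 higher, a median of 3.15 and all 13 with KO above all WT values (Fisher's exact test, adjusted p = 2.1e-04). Between 45 and 47 Krtap genes were higher under the scaling and background alternatives, 32 with slide as a block (median 4.34) and 0 with the replicate block (median 4.39). With slide as a block 12 Krt genes and 0 Sprr genes were higher, with medians of 1.15 and 3.09. Without 1 mouse the counts were 34 to 46 for Krtap (lowest without KO 2), 14 to 19 for Krt (lowest without WT 2) and 1 to 5 for Sprr (lowest without WT 2). Genes of a family with near-identical sequences can share signal on a probe, and the counts treat them as separate.

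Red blood cell transcripts were measured for 4 of 8 genes and not tested as a list (median 0.66). Of the 4, 2 rose, and 2, Hbb-b2 and Alas2, named after their values were seen, were lower in the mean (-1.26 and -0.57) and did not pass. The mean of the 4, relative to the WT mean, was 0.32, -0.12 and -0.21 in WT 1, 2 and 3 and 1.25, -0.56 and 0.89 in KO 1, 2 and 7, so the groups overlap. Slc4a1, the gene of the band 3 anion exchanger, rose by 2.05 ± 0.32 (SE, adjusted p = 0.031), and Ahsp, a chaperone gene of alpha globin, by a fitted 1.89 ± 0.31 (adjusted p = 0.038), although it was well above background on only 1 of 3 WT arrays, so the size of its rise is uncertain. Within slide 1 Slc4a1 differed by 2.64, and with slide as a block it passed (adjusted p = 0.047) and Ahsp did not (adjusted p = 0.099). Slc4a1 did not pass without WT 1, WT 2, WT 3 or KO 7, nor Ahsp without WT 2, WT 3 or KO 2, with highest adjusted p of 0.12 and 0.15.

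The rise of hair follicle and shaft genes was weighed first. A slide effect as its cause is argued against by KO 1, which lay above the 3 WT arrays of its own slide by a list median of 4.16 (4.06 with bounds), with a gap of 2.82 above the highest WT array against a WT range of 0.80. More follicle tissue in the KO pieces would raise genes of the resting follicle. The 13 such genes, however, had a median of 0.05 (0.0525, SD of members 0.36). Of these, 9 were higher in the mean and 0 passed. Other lists also hold 3 of them: Krt15 (basal keratinocyte), Krt79 (sebaceous gland) and Sox9 (cartilage). Genes also made outside the follicle would rise less with added follicle tissue, so a smaller increase of it is not excluded. More follicles in the growth phase may remain a candidate explanation: 9 of 12 growth phase regulators were higher, with a median of 0.37 (0.365). This median lay between the bounds set beforehand. The hair list itself holds 4 of the 12, Lef1, Hoxc13, Msx2 and Foxn1, all higher in the mean. Of the 12, only Lef1 and Hoxc13 rose. These 4 are thus part of the pattern to be explained and no separate support. Lower in the mean were Bmp4 (-0.48), Dlx2 (-0.35) and Wnt10a (-0.06). All these genes were named after their values were seen. The 31 cell cycle genes had a median of 0.03 and 0 rose, so that list gives no separate support either. Hair cycle phase differs with age and between mice, and the 2 groups had 3 mice each. A difference in growth phase therefore stays open beside an effect of the deleted segment, which was not tested.

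The lower adipocyte and muscle markers were weighed next. Dilution by follicle and epidermal transcripts would lower other dermal genes alike. The fibroblast list had a median of 0.30 and the endothelial list of 0.27, but both were highest in KO 7. The list means relative to WT in KO 1, 2 and 7 were 0.01, 0.02 and 0.54 for fibroblast genes. For endothelial genes they were 0.13, -0.05 and 0.41. Without KO 7 the medians were 0.05 for fibroblast and 0.07 for endothelial genes. The endothelial median fell further, to -0.08, when another mouse was left out. The fibroblast median lay above that of the adipocyte list by at least 0.82 in each fit without 1 mouse (SD of members 0.71). The endothelial median did so by at least 0.87 (SD of members 0.43). These gaps argue against dilution as the only cause for adipocyte markers, though only weakly. The SD of members is a spread between genes and not between mice. Among WT mice the adipocyte list mean ranged over 1.36, against a difference between the groups of -0.88. Within slide 1, which rests on KO 1, the medians were -0.01 for fibroblast, 0.13 for endothelial and -0.37 for adipocyte genes. The fibroblast gap there was smaller than the SD of members, so the argument is weaker for KO 1. For muscle markers the fibroblast gap fell to 0.18 without KO 7, so dilution stays open there, as does a smaller share of it elsewhere: cartilage markers were also lower (median -0.26), and 10 of 11 Schwann cell and nerve markers were. A different share of fat and muscle layers between single ear pieces is consistent with the spread within groups: the range of the list mean was 1.55 times the difference between WT and KO among WT mice and 0.85 times among KO mice for adipocyte markers, and 2.06 and 2.16 times for muscle markers. An effect of the deletion on these tissues was not tested apart from it.

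The rise of neutrophil markers was weighed last. KO 1 lay above the WT arrays of its slide by a list median of 1.82, with a gap of 1.48 above the highest WT array against a WT range of 0.65, which argues against slide as the cause. Keratinocytes also make S100a8, S100a9 and Lcn2, but 14 neutrophil genes not listed as keratinocyte genes had a median of 1.91 (SD of members 1.77), 12 of them were higher and 1, Cxcr2, rose (named after its value was seen). The mean of these 14 genes in the lowest KO array lay 1.04 above the highest WT array against a WT range of 0.87, which argues against keratinocytes as the only source, although 7 of the 14 are also in the neutrophil list and Ly6g differed by -0.35 (adjusted p = 0.19). More neutrophils in KO skin may be a candidate explanation for that part (1.91), and no cell count was used here.

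The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10, the real one, gave as many genes as the 560 that passed, and the highest of the others gave 0. Every other split mixes WT and KO mice in each set, which puts the group difference into the spread. Few calls were therefore likely in advance, and the 0 excludes neither chance nor slide.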
